A study of Mus musculus with 12 samples.

How the data were processed

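RNA was sequenced from 12 libraries of GC1 cells, an established mouse spermatogonial line, all labelled 24 h. Each of 4 groups held 3 libraries: wild-type cells, Ythdf2 knockout cells, knockout cells carrying an overexpression control, and knockout cells overexpressing Setdb1. The labels number the libraries of a group 1 to 3 and do not say whether these came from separate cultures. The p-values therefore measure the spread between these libraries, which can be technical.

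The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 2281 genes, with 1 column per library. Total RNA was extracted with a phenol-based reagent and libraries followed a standard Illumina protocol, per the labels' protocols. Cutadapt, HISAT2, StringTie, edgeR and DESeq2 are named per the submitters' processing notes, which give no role or version. The genome build and the annotation release are not given in the sources used here, and no coordinates are printed. Read counts were not used here, so depth is unknown and no counting interval is given. The lowest value in the table was 1e-04 FPKM, which stood in place of 0.

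The table is a preselected set of genes. In the authors' deposited table all 2281 genes were marked significant, with 1 deposited p-value and 1 q-value per gene for a comparison that the column names do not give. The highest p in the authors' deposited table was 0.05, the highest q was 0.113, and 368 genes had a q above 0.05. Each gene also carried at least 1 of 25 Gene Ontology target terms chosen by the submitters. The ranks of the deposited p-values correlated across genes at a Spearman rho of 0.7 with those of a test over all 4 groups. The rho was 0.49 for knockout against wild type, 0.33 for Setdb1 overexpression against its control and 0.14 for the control against the unmodified knockout. Counts of changed genes, percentages and adjusted p-values therefore describe this set and not the transcriptome, and the high share of changed genes is a property of how the set was made. Setdb1 and other genes without a value here were not analysed here.

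The 2281 Ensembl gene IDs all matched a symbol in GENCODE M21, and 14116 of the 14185 transcript IDs in the table were found in that release. Transcript GC content, transcript length and 3′ UTR sequence were taken from it.

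The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That design assumed a table of the whole transcriptome, and it was kept as written for the preselected table. Values were analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 libraries were tested, which kept 2063 genes and left out 218. Fold changes are differences on the log2(FPKM + 1) scale, which understates the change of genes with low values. A linear model with 1 mean per group was fitted over all 12 libraries with limma-trend (limma 3.58.1 in R 4.3.3), which shares 1 estimate of the spread between the 4 groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 2063 genes of each comparison, and an adjusted p under 0.05 counted as a change. The words rose and fell are used only of genes or lists past that threshold. Values are given as mean ± SD over 3 libraries unless an SE of the log2 fold change is named.

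The comparisons were 3: knockout against wild type, overexpression control against unmodified knockout, and Setdb1 overexpression against overexpression control. The first and the last share no library, and the overlap of their changed genes was tested in each of the 4 combinations of direction by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 4. Pairs of comparisons that share libraries were not compared by overlap, except in an alternative with the overexpression control in place of the knockout.

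The 34 gene lists covered the m6A machinery, H3K9 methylation and heterochromatin, 4 lists of DNA repair and damage signalling, p53 targets, apoptosis, replication, mitosis, interferon, stress, metabolic, cytoskeletal and adhesion genes, ribosomal and mitochondrial genes, and markers of germ cells, testis somatic cells, fibroblasts, epithelia, leukocytes and endothelium. The 25 lists with at least 5 tested members were tested with camera in limma, which compares the members with the other tested genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 25. The test was repeated with a correlation estimated from the data. Counts of members that rose or fell are those of the adjustment over all 2063 genes, and counts adjusted over the list alone are given beside them. Not all fixed members were tested. Tested were 31 of 46 mitosis genes, 29 of 48 of replication, 21 of 49 of homologous recombination and 8 of 22 of end joining. For hypoxia 11 of 37 were tested and for the stress response 13 of 42. Counts therefore describe the tested members of a preselected set and not whole pathways. The submitters' 25 target terms were tested in the same way. They were chosen with these libraries and are not independent evidence.

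The named genes were Ythdf2, the 8 largest rises and the 8 largest falls in each comparison, and up to 4 members per list with the smallest adjusted p. The largest rises and falls had to pass the threshold, to reach a mean of 5 FPKM in the higher group and to have no overlap between the libraries of the compared groups. Predicted genes were left out, and some genes that the rule would name are not reported here. For the overlap, the 6 genes with opposite changes and the 4 with the same direction were named whose smaller absolute log2 fold change was largest. Genes named outside this rule are said to be so. For Ythdf2 an exact permutation test was added, which with 3 libraries against 3 cannot give a p below 0.1.

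The procedure was tested on simulated values made from the means and spread of the 2063 genes in the comparison of knockout with wild type. Of 50 genes planted at each size, 68% were recovered at 1.25-fold, 92% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 8 calls among 1833 unchanged genes. A planted list of 30 genes was recovered, and 0 of 24 random lists passed the threshold in camera. The simulated errors were independent between genes, and most genes were left unchanged. The simulation therefore does not give the error rate of the list tests on the real values, where genes may vary together and most changed.

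The correlation of log values was 0.974 to 0.996 between libraries of a group and 0.933 to 0.994 between groups. The labels give no batch. Blood cell transcripts, recognised from a list of red cell, neutrophil, platelet and leukocyte markers written after these transcripts were seen, set 4 libraries apart. These were the libraries with a mean haemoglobin value above 10 FPKM.

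The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a model of only the 6 libraries compared, the replicate number as a block, array weights, a minimum log2 fold change of 1, an estimated correlation for the lists, another comparator, and leaving out each library in turn. Chosen after the data were seen were a model term for the 4 libraries with blood transcripts, their removal, a fit with them as the only wild-type and knockout libraries, adjustment over all 21951 protein-coding genes of GENCODE M21, and removal of each library's trend with GC content and length (loess, span 0.5). Permutation tests across genes used 1e+05 resamples with a fixed seed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.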

Results

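RNA-seq was performed on 12 libraries of GC1 cells, a mouse line derived from spermatogonia. Wild-type cells, Ythdf2 knockout cells, knockout cells with an overexpression control and knockout cells overexpressing Setdb1 were each represented by 3 libraries. Ythdf2 encodes a reader protein that binds m6A-modified RNA, and Setdb1 encodes a histone H3K9 methyltransferase. The series concerns the role of both proteins in DNA damage repair. FPKM values of 2281 preselected genes were analysed, of which 2063 were tested. The values of these genes summed to between 75955 and 81924 FPKM per library, and between 2007 and 2024 genes per library reached 1 FPKM. Read depth is unknown.

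The transcript of the targeted gene was lower in all knockout groups and was not lost. Ythdf2 stood at 9.0 ± 0.43 FPKM in wild-type cells, 6.05 ± 0.244 in the knockout, 6.14 ± 0.103 in the overexpression control and 4.63 ± 0.383 with Setdb1 overexpression (SD, 3 libraries each). It fell by 0.50 on the log2 scale in the knockout (SE 0.05, adjusted p = 8.75e-06), a mean change of -32.8%. It fell by a further 0.34 with Setdb1 overexpression against the control (SE 0.05, adjusted p = 0.000189), a mean change of -24.6%. The control and the unmodified knockout differed by 0.02 (adjusted p = 0.876). All 3 knockout libraries lay below all 3 wild-type libraries (two-sided exact permutation p = 0.1, the smallest possible). The edited site is not given in the sources used here, and an RNA level does not measure the protein.

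**Figure D1:**
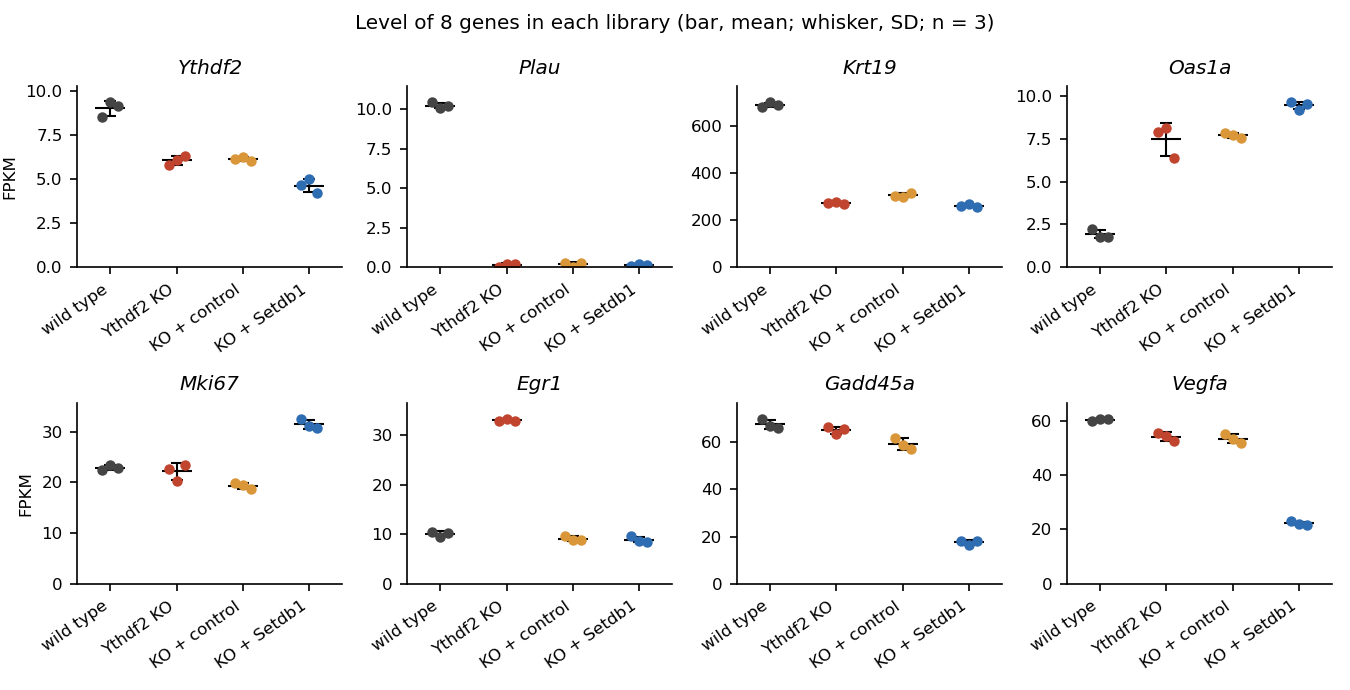
FPKM of 8 genes in each of the 12 libraries, with 1 point per library, a bar at the group mean and whiskers of 1 SD (n = 3). Plau, Krt19 and Oas1a separated wild type from all 3 knockout groups, Egr1 was high in the unmodified knockout at 33 FPKM, and Gadd45a and Vegfa were low with Setdb1 overexpression at 17.5 and 22.2 FPKM.

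The comparison of knockout with wild type asked which transcripts changed with knockout of the m6A reader gene. The labels give all knockout groups the same line code, so an effect of Ythdf2 cannot be told from other differences between the lines. Genes of mitosis and of DNA replication were lower in the knockout, interferon-stimulated genes were higher, and several epithelial genes were much lower. Plau, which encodes urokinase plasminogen activator, went from 10.2 ± 0.186 to 0.154 ± 0.0945 FPKM and fell by 3.29 on the log2 scale (SE 0.08, adjusted p = 9.54e-10). The other large falls were Spon2 (-2.00), Eya2 (-1.84), Plet1 (-1.81), the scavenger receptor gene Olr1 (-1.78), the tetraspanin gene Tspan8 (-1.74), Krt8 (-1.72) and the retinol carrier gene Rbp4 (-1.72), with SEs of 0.05 to 0.16. The immediate early gene Egr1 rose by 1.62 from 10.1 ± 0.501 to 33 ± 0.228 FPKM. In the overexpression control Egr1 stood at 9.08 ± 0.477 FPKM. The other large rises were Oas1a (1.52), Ass1, an enzyme of arginine synthesis (1.51), the inhibin subunit gene Inhbb (1.44), Irgm1 (1.05), Pcdh7 (1.04), the mitochondrially encoded mt-Nd3 (1.01) and Ifit1 (0.96). Pcdh7 was uneven between the wild-type libraries (6.01 ± 3.66 FPKM, adjusted p = 0.0349), and its call was lost on leaving out wild-type library 2 or 3 or any 1 of the knockout libraries, with adjusted p = 0.127 without wild-type library 2. Among the 2063 genes, 779 rose and 815 fell, 77.3% in all, with a median absolute log2 fold change of 0.30 among those that changed. An absolute change of at least 1 on the log2(FPKM + 1) scale was reached by 10 genes that rose and 36 that fell.

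In the mitosis list, 29 of 31 tested members fell and 1 rose. DNA topoisomerase gene Top2a went from 54 ± 0.476 to 35.2 ± 0.727 FPKM (log2 fold change -0.60), and Anln (-0.66), the spindle motor gene Kif11 (-0.63) and the checkpoint kinase gene Bub1b (-0.47) also fell. In the list of DNA replication and S phase, 26 of 29 members fell and 1 rose. Uhrf1, which belongs to this list and to that of heterochromatin, went from 48.5 ± 0.828 to 31.2 ± 0.179 FPKM (-0.62), and the replicative helicase genes Mcm4 (-0.44), Mcm5 (-0.32) and Mcm6 (-0.24) fell. In camera the adjusted p was 3.63e-06 for mitosis, with a median log2 fold change of -0.37, and 2.41e-05 for replication, with a median of -0.28. Both lists passed with an estimated correlation, each at adjusted p = 0.0238.

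Of 23 interferon-stimulated genes, 18 rose and 3 fell. The oligoadenylate synthetase genes Oas1a and Oas1g went from 1.94 ± 0.252 to 7.47 ± 0.97 FPKM and from 0.977 ± 0.0442 to 4.2 ± 0.0475 FPKM. The immunity GTPase gene Irgm1 and the RNA sensor gene Ddx58 rose by 1.05 and 0.61 on the log2 scale. The median was 0.59 (adjusted p = 0.000416 in camera and adjusted p = 0.0238 with an estimated correlation). Oas1a and Oas1g are close paralogs, and reads shared between them cannot be resolved in FPKM values.

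Of 24 p53 target genes, 18 rose and 2 fell, with a median of 0.31 (adjusted p = 0.00313 in camera and adjusted p = 0.0756 with an estimated correlation). The cyclin gene Ccng1 went from 72.1 ± 1.5 to 110 ± 1.36 FPKM, and Trp53inp1 (0.58) and Btg2 (0.51) rose, while the kinase gene Plk2 fell (-0.37). Of 21 genes of homologous recombination and Fanconi anaemia repair, 15 fell and 2 rose, with a median of -0.32 (adjusted p = 0.0177 in camera and adjusted p = 0.0756 with an estimated correlation). Sfr1 went from 82.1 ± 3.18 to 51.7 ± 2.28 FPKM (-0.66). The polymerase gene Polq (-0.58) and Bard1 (-0.50) fell, and the endonuclease gene Mus81 rose from 7.15 ± 0.181 to 10.1 ± 0.259 FPKM (0.44).

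Of 6 epithelial markers, 5 fell and 0 rose, with a median of -1.16 (adjusted p = 0.0229 in camera and adjusted p = 0.0898 with an estimated correlation). The keratin genes Krt19 and Krt14 went from 692 ± 9.56 to 274 ± 3.98 FPKM and from 152 ± 7.33 to 74.1 ± 1.38 FPKM, and the epithelial transcription factor gene Elf3 fell by 1.30. Of 19 nuclear genes of oxidative phosphorylation, 11 rose and 2 fell, with a median of 0.20 (adjusted p = 0.0274 in camera and adjusted p = 0.382 with an estimated correlation). The complex I genes Ndufa8 and Ndufb6 rose by 0.59 and 0.58. Without the 4 libraries that carried blood transcripts the epithelial and oxidative phosphorylation lists missed the threshold (adjusted p = 0.0737 and 0.0771), which left 1 library per group, assumed to vary like the others. The oxidative phosphorylation list also missed it after the trend with GC content and length was removed (adjusted p = 0.119).

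The remaining 18 lists did not pass in camera in the knockout, with adjusted p of 0.173 to 0.871. Of 9 genes of H3K9 methylation and heterochromatin, 6 fell, among them Cbx5 (-0.36) and Dnmt1 (-0.23), and Trim28 rose (0.27). Of 14 DNA damage signalling genes, 8 fell and 3 rose, with Smc3 and Topbp1 at -0.35 and -0.23 and Rnf169 at 0.32. Of 8 genes of non-homologous end joining 3 fell and 2 rose, and of 15 genes of excision and mismatch repair 6 fell and 6 rose. Of 7 genes of the m6A machinery, 4 rose, among them the writer complex gene Virma (0.33), and 3 fell, among them Ythdf2. Of 7 spermatogonial stem and progenitor markers 5 fell, including Cd9 (-0.77), Bcl6b (-0.51) and Itga6 (-0.36), and Foxo1 rose (0.29). Of 12 fibroblast markers 8 rose and 4 fell, with Thbs1 at 0.80 and Fstl1 at 0.62. Of 16 genes of integrins, cadherins and laminins, 8 fell and 6 rose, with Itgb7 at -1.55 and Nid1 at -1.44. Members rose and fell in the lists of apoptosis (4 and 3 of 12), inflammation (3 and 5 of 10), immediate early and heat shock genes (8 and 6 of 19), the unfolded protein and integrated stress response (5 and 6 of 13), hypoxia and glycolysis (3 and 5 of 11), cholesterol synthesis (6 and 3 of 15), actin and SRF targets (5 and 1 of 10), ribosomal proteins (10 and 5 of 19), mitochondrially encoded transcripts (3 and 2 of 6) and Zfp zinc finger genes (12 and 5 of 29). The median and the mean differed in sign for the m6A machinery and for cholesterol synthesis. Adjusted over the list alone, the counts were the same except that 4 interferon-stimulated genes fell and 4 hypoxia genes rose.

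**Figure D2:**
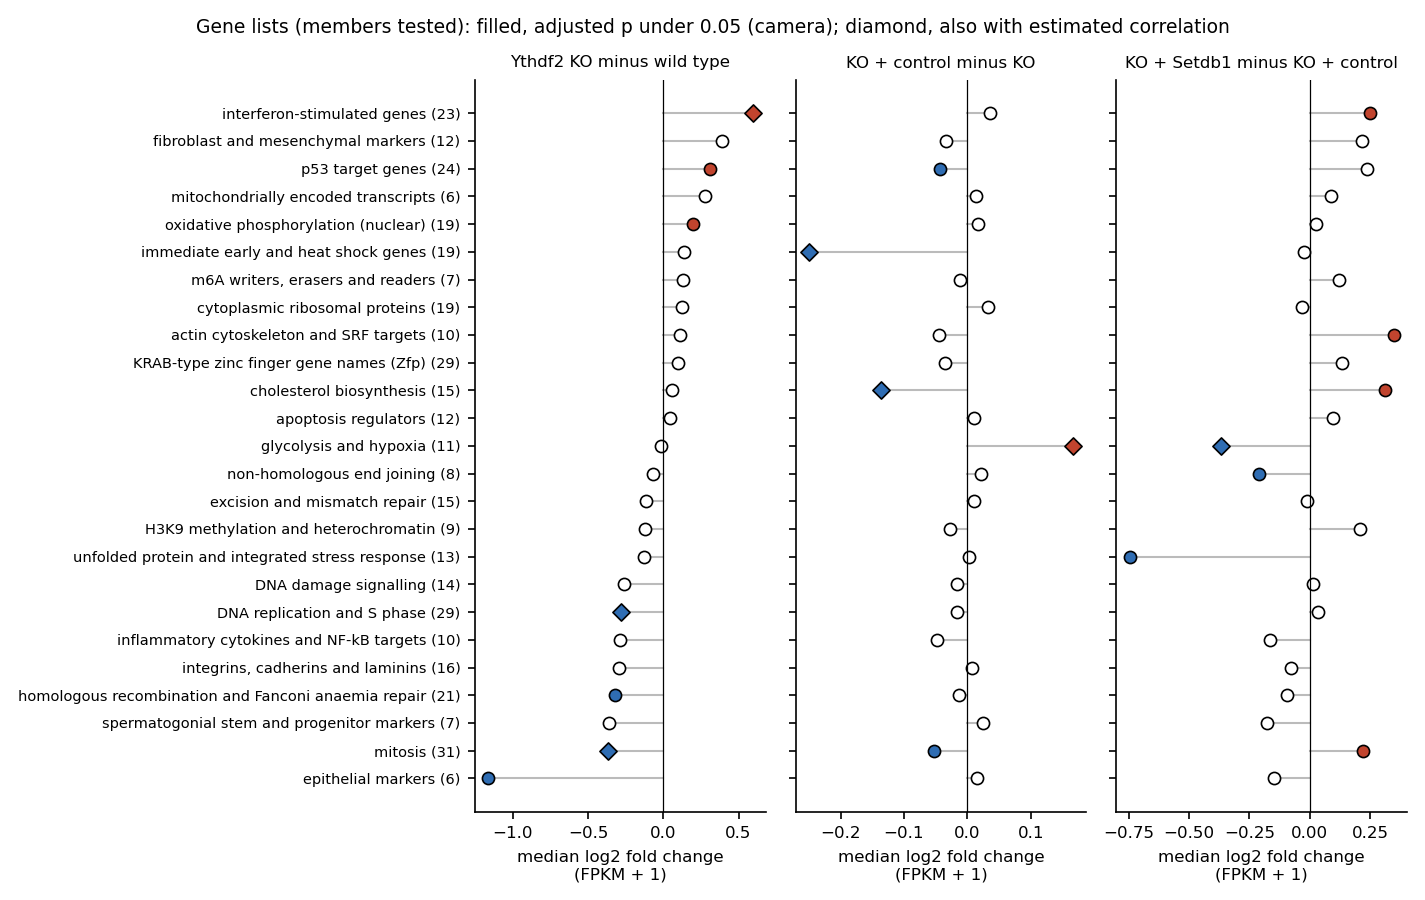
Median log2 fold change (FPKM + 1) of the 25 tested gene lists in 3 comparisons, with the members tested in brackets and a different horizontal range in each panel. Filled symbols passed the threshold in camera (7, 5 and 7 lists from left to right), and diamonds also passed with an estimated correlation (3, 3 and 1 lists).

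Red cell, neutrophil and platelet transcripts were present in 4 libraries. The mean of the haemoglobin genes was 128 and 51.2 FPKM in wild-type libraries 2 and 3 and 150 and 45.1 FPKM in knockout libraries 1 and 2. It was 1.28 FPKM in wild-type library 1, 0.0307 FPKM in knockout library 3 and at most 0.147 FPKM in the 6 overexpression libraries. The haemoglobin genes Hbb-bs and Hba-a2 did not pass the test in the knockout (adjusted p = 0.842 and 0.821). With these 4 as the only wild-type and knockout libraries in the model, 1475 genes changed in the knockout.

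**Figure D3:**
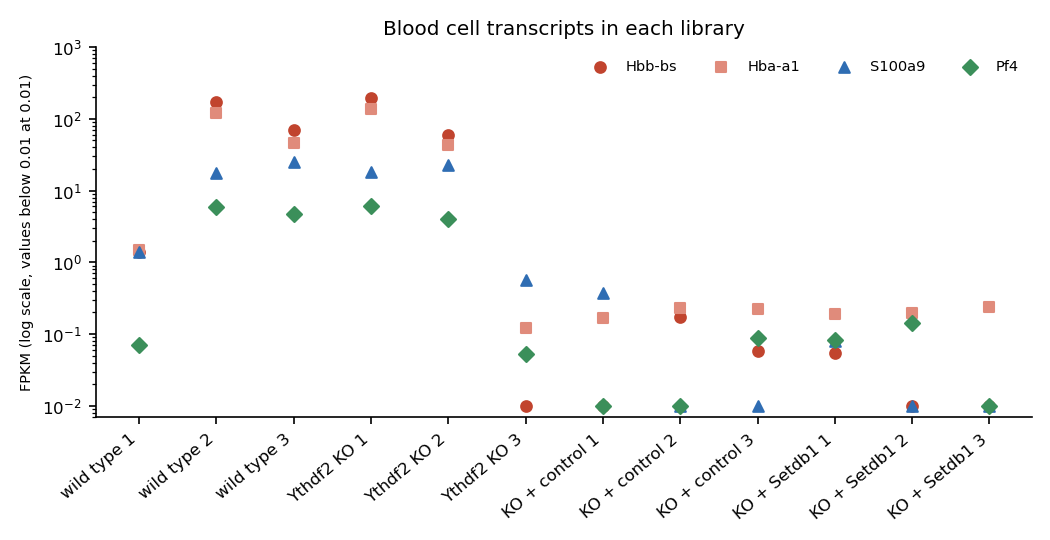
FPKM of the red cell genes Hbb-bs and Hba-a1, the neutrophil gene S100a9 and the platelet gene Pf4 in each of the 12 libraries, on a log axis with values below 0.01 drawn at 0.01. Wild-type libraries 2 and 3 and knockout libraries 1 and 2 stand above the rest for all 4 genes.

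The comparison of the overexpression control with the unmodified knockout asked how cells with the control construct differed from cells without it. Immediate early genes and cholesterol synthesis genes were lower in the control and hypoxia genes were higher. Of 19 immediate early and heat shock genes, 11 fell and 1 rose, with a median of -0.25 (adjusted p = 9e-09 in camera and adjusted p = 0.00454 with an estimated correlation). Egr1 fell by 1.75 (SE 0.05, adjusted p = 1.03e-08), Fos went from 7.34 ± 0.416 to 2.25 ± 0.472 FPKM (-1.37), and the phosphatase genes Dusp1 (-0.78) and Dusp6 (-0.45) fell. Of 11 genes of hypoxia and glycolysis 7 rose and 0 fell, with Ero1l at 0.32 and the oxygen sensor gene Egln3 at 0.25, and a median of 0.17 (adjusted p = 1.06e-06 in camera and adjusted p = 0.00454 with an estimated correlation). Of 15 cholesterol synthesis genes 7 fell and 0 rose, with a median of -0.14 (adjusted p = 1.87e-06 in camera and adjusted p = 0.00454 with an estimated correlation). The mitosis list, with 6 of 31 members lower and a median of -0.05, had adjusted p = 0.000858 in camera and adjusted p = 0.0964 with an estimated correlation. The p53 targets, with 5 of 24 lower and a median of -0.04, had adjusted p = 0.0131 in camera and adjusted p = 0.144 with an estimated correlation. Adjusted over the list alone, 12 immediate early genes, 11 cholesterol genes, 8 mitosis genes and 7 p53 targets fell and 7 hypoxia genes rose. These lists moved between a group in which 2 of 3 libraries carried blood transcripts and a group in which none did. The same 5 lists passed in the same direction with a model term for these libraries. A fit without these libraries left 1 unmodified knockout library, with its spread taken from the other groups, and adds little for these lists. The other 20 lists did not pass (adjusted p of 0.194 to 0.959). The smallest adjusted p in limma was 0.087 among the genes of homologous recombination (Rad54b, -0.23), 0.0596 among those of excision and mismatch repair (Neil3, -0.20) and 0.0528 among those of DNA damage signalling (Babam2, 0.20). Babam2 passed without knockout library 1 (adjusted p = 0.00901) and with median-of-ratios scaling or quantile normalization (adjusted p = 0.0437 and 0.049).

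Among all tested genes, 75 rose and 104 fell in the control, 8.7% in all, and 506 had an unadjusted p under 0.05. Beside the immediate early genes, Taf4 (-0.63), the signalling inhibitor gene Spry2 (-0.53) and Zfp36 (-0.47) fell, and Hmgn3 (0.39), the beta-oxidation gene Hadhb (0.31) and Kctd11 (0.29) rose. Impdh1 (0.52) and Limk1 (-0.46) lost the call on leaving out any 1 of the 6 libraries, with adjusted p up to 0.108 and 0.101. Hist1h1c (-0.56) lost it without knockout library 1 or 2 or control library 1 or 2, Ccnk (0.42) without any 1 library other than control library 3, and Naaa (0.35) without any 1 other than control library 1, with adjusted p up to 0.0824, 0.0949 and 0.144. Spry2, Zfp36, Hmgn3 and Kctd11 also missed the threshold without the libraries with blood transcripts, a fit that left 1 unmodified knockout library. The count was 66 with a model term for the libraries with blood transcripts and 41 without those libraries. The share of rises among the changed genes was 41.9%, and it was 51.4% with median-of-ratios scaling, 52.7% with quantile normalization and 54.2% after removal of the trend with GC content and length.

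The comparison of Setdb1 overexpression with the overexpression control asked what the methyltransferase changed in knockout cells. Setdb1 itself was not analysed here, so its overexpression is taken from the labels and was not checked. In camera at the preset correlation, the lists of hypoxia, of the integrated stress response and of non-homologous end joining were lower with Setdb1, and those of mitosis, cholesterol synthesis, interferon-stimulated and actin genes were higher. With an estimated correlation the hypoxia list kept its call (adjusted p = 0.0255) and the others did not (adjusted p of 0.0638 to 0.074). Against the unmodified knockout the hypoxia list also missed the threshold in camera with an estimated correlation (adjusted p = 0.0503). Gadd45a, a growth arrest gene induced by DNA damage and other stress, went from 59.2 ± 2.44 to 17.5 ± 0.977 FPKM and fell by 1.70 on the log2 scale (SE 0.04, adjusted p = 2.78e-10). Ddit3, a transcription factor gene of the stress response, fell by 1.51 from 66.5 ± 1.79 to 22.8 ± 1.21 FPKM. The other large falls were Ero1l (-1.25), the angiogenic factor gene Vegfa (-1.23), the mitochondrial folate enzyme gene Mthfd2 (-1.19), the nitric oxide synthase gene Nos2 (-1.17), Zbtb42 (-1.27) and H6pd (-1.20). Zbtb42 was uneven with Setdb1 (2.25 ± 2.29 FPKM). H6pd passed narrowly (adjusted p = 0.0489) and lost the call on leaving out any 1 control library or Setdb1 library 1 or 2, with adjusted p up to 0.149. The large rises were the keratin gene Krt6a (1.42), Ifi27l2a (1.10), the aldehyde dehydrogenase gene Aldh3a1 (0.83), Csrp2 (0.76), Thbs1 (0.75), Atg9b (0.74) and Wdr6 (0.74), with SEs of 0.03 to 0.18. Among the 2063 genes, 744 rose and 656 fell, 67.9% in all, with a median absolute log2 fold change of 0.26 among those that changed. An absolute change of at least 1 on the log2(FPKM + 1) scale was reached by 4 genes that rose and 22 that fell.

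Of 11 genes of hypoxia and glycolysis, 10 fell and 0 rose with Setdb1, with a median of -0.37 (adjusted p = 4.42e-05 in camera and adjusted p = 0.0255 with an estimated correlation). Ndrg1 went from 159 ± 1.04 to 71.1 ± 0.864 FPKM (-1.15), and the glycolytic gene Aldoc fell by 0.57. Of 13 genes of the unfolded protein and integrated stress response, 9 fell and 4 rose, with a median of -0.75 (adjusted p = 0.0161 in camera and adjusted p = 0.0663 with an estimated correlation). The cystine transporter gene Slc7a11 went from 4.92 ± 0.097 to 1.27 ± 0.028 FPKM (-1.38), and the mitochondrial folate gene Aldh1l2 fell by 1.14. Of 8 genes of non-homologous end joining 7 fell and 0 rose, with a median of -0.21 (adjusted p = 0.0161 in camera and adjusted p = 0.0663 with an estimated correlation). Xrcc6, which encodes the Ku70 subunit, went from 20.5 ± 0.29 to 15.2 ± 0.429 FPKM (-0.41), and Aptx (-0.39), Cyren, an inhibitor of end joining (-0.34), and the DNA-dependent kinase gene Prkdc (-0.22) fell.

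Of 31 mitosis genes, 23 rose and 1 fell with Setdb1, with a median of 0.22 (adjusted p = 0.0003 in camera and adjusted p = 0.0638 with an estimated correlation). The proliferation marker Mki67 went from 19.3 ± 0.608 to 31.4 ± 0.949 FPKM (0.67), and the mitotic kinase gene Plk1 (0.62), Anln (0.54) and Cenpf (0.47) rose. Of 15 cholesterol synthesis genes 12 rose and 2 fell, with a median of 0.31 (adjusted p = 0.00369 in camera and adjusted p = 0.0638 with an estimated correlation). Against the unmodified knockout the median of this list was 0.16, with 9 members higher and 1 lower. There it missed the threshold in camera (adjusted p = 0.0649), since the control itself lay below the unmodified knockout (median -0.14). The desaturase gene Scd1 rose by 0.31. Of 23 interferon-stimulated genes 16 rose and 2 fell, with a median of 0.25 (adjusted p = 0.0156 in camera and adjusted p = 0.0638 with an estimated correlation), among them Irf7 (0.55), Irgm1 (0.52) and the kinase gene Eif2ak2 (0.47). Of 10 actin and SRF target genes 8 rose and 0 fell, with a median of 0.35 (adjusted p = 0.0213 in camera and adjusted p = 0.074 with an estimated correlation), among them Cnn2 (0.58), Actn1 (0.36) and Myh9 (0.34).

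The remaining 18 lists did not pass in camera with Setdb1, with adjusted p of 0.103 to 0.945. Of 9 genes of H3K9 methylation and heterochromatin 6 rose and 1 fell, with the methyltransferase gene Suv39h1 at 0.36 and the demethylase gene Kdm4a at -0.42. Of 21 genes of homologous recombination and Fanconi anaemia repair 6 rose and 7 fell, with Fanca at 0.34, Polq at 0.33 and Mus81 at -0.28. Of 14 DNA damage signalling genes 4 rose and 4 fell, with Rnf169 at 0.35 and Rad9a at -0.53, and of 15 genes of excision and mismatch repair 5 rose and 6 fell. Of 24 p53 targets 16 rose, among them Ccng1 (0.49), and 5 fell, among them Gadd45a and Sesn2 (-0.83). Immediate early and heat shock genes went both ways, with 7 of 19 higher and 7 lower, and the lower ones included the haem oxygenase gene Hmox1, from 109 ± 1.07 to 50.3 ± 0.536 FPKM, and Atf3 (-1.17). Members rose and fell in the lists of the m6A machinery (3 and 2 of 7), apoptosis (6 and 2 of 12), DNA replication (12 and 7 of 29), spermatogonial markers (1 and 5 of 7), fibroblast markers (8 and 3 of 12), epithelial markers (1 and 3 of 6), inflammation (2 and 5 of 10), integrins, cadherins and laminins (5 and 9 of 16), ribosomal proteins (3 and 5 of 19), mitochondrially encoded transcripts (3 and 0 of 6), nuclear oxidative phosphorylation (9 and 6 of 19) and Zfp zinc finger genes (16 and 5 of 29). The median and the mean differed in sign for DNA damage signalling and for apoptosis. Adjusted over the list alone, the counts were the same except for interferon-stimulated genes (17 rose and 3 fell), excision and mismatch repair (6 and 6), fibroblast markers (9 and 3) and ribosomal proteins (2 and 2).

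The knockout and the Setdb1 comparison share no library, so their changes could be set against each other directly. Krt6a, Aldh3a1, Eya2 and Olr1 fell in the knockout and rose with Setdb1. Krt6a stood at 4.3 ± 0.488 FPKM in wild type, 1.49 ± 0.101 in the knockout, 1.3 ± 0.0289 in the control and 5.17 ± 0.241 with Setdb1. Aldh3a1 stood at 15.5 ± 1.01, 7.86 ± 0.448, 7.89 ± 0.607 and 14.8 ± 0.82 FPKM in the same order. The clock output gene Dbp rose in the knockout (0.85) and fell with Setdb1 (-0.80), as did Wdr81 (0.77 and -0.79). Wdr81 was uneven between libraries (adjusted p = 0.0195 and 0.0203), and its call was lost in the knockout without wild-type library 1 (adjusted p = 0.077) and with Setdb1 without control library 1 or 3 or Setdb1 library 3 (adjusted p up to 0.0793). Txnip fell in both comparisons (-1.28 and -1.17), as did Aldh1l2 (-0.90 and -1.14) and Nos2 (-0.84 and -1.17), and Thbs1 rose in both (0.80 and 0.75).

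Across all genes the changes with Setdb1 were not the reverse of those in the knockout. Of 1053 genes that changed in both comparisons, 507 changed in opposite directions and 546 in the same direction. If the changes were independent, 293.9 genes lower in the knockout would have risen with Setdb1, and 275 did (one-sided Fisher's exact p = 0.966, adjusted p = 0.966). For genes higher in the knockout and lower with Setdb1, 247.7 would be found by independence and 232 were (Fisher's exact p = 0.943, adjusted p = 0.966). The counts in the same direction were 257 lower in both, against 259.2 (Fisher's exact p = 0.601), and 289 higher in both, against 280.9 (Fisher's exact p = 0.237). Independence is not a strict baseline among genes preselected as significant, so these counts were not read as above or below chance. Across the tested genes, which are not independent replicates, the log2 fold changes correlated at a Pearson r of 0.01 and a Spearman rho of 0.00.

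**Figure D4:**
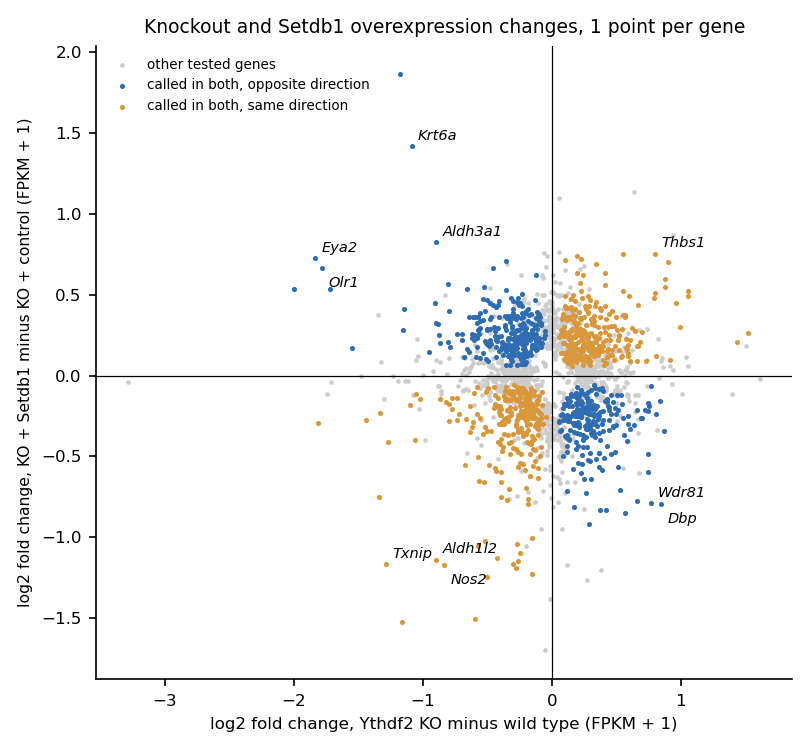
Log2 fold change (FPKM + 1) of each of the 2063 tested genes in the knockout against wild type (horizontal) and with Setdb1 overexpression against its control (vertical), with the 10 named genes labelled. The 507 genes that changed in opposite directions (blue) and the 546 that changed in the same direction (orange) filled the 4 quadrants in similar numbers.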

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

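The model term for the 4 libraries with blood transcripts, their removal, the fit with them as the only wild-type and knockout libraries, the adjustment over all protein-coding genes and the removal of the trend with GC content and length were chosen only after the results were seen. Tests on read counts, listed among the alternatives, were not run because counts were not used here.

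The counts of changed genes in the knockout (1594) and with Setdb1 (1400) stayed within 1.5 times under the alternatives run, except that a minimum absolute log2 fold change of 1 left 46 and 26 genes, and 2 in the overexpression control. The lowest other counts were 1127 in the knockout, without the libraries with blood transcripts, and 1009 with Setdb1, with adjustment over all protein-coding genes. On leaving out each library in turn the knockout gave 1526 to 1552 genes, Setdb1 1305 to 1331 and the overlap in opposite directions 473 to 497. That overlap was 299 with adjustment over all protein-coding genes, where more genes enter the adjustment. With the overexpression control in place of the knockout it was 550, with 491 genes in the same direction and 544.4 opposite by independence. There both comparisons use the control libraries, so their changes are not independent and the balance was not interpreted. The count for the overexpression control (179) was the least stable. It was 106 in a model of only the 6 libraries compared, 66 with the blood term, 41 without the libraries with blood transcripts and 53 with adjustment over all protein-coding genes. It was 96, 106 and 128 without knockout library 1, 2 or 3 and 119, 93 and 117 without control library 1, 2 or 3, so the range was 93 to 128. Fewer libraries or more genes entered each of these fits except that with the blood term. Blood transcripts marked 2 of 3 unmodified knockout libraries and no control library, so that term overlaps this comparison and widens its error. In the comparison of knockout with wild type, where they were balanced, the term left 1587 changed genes. How much of the drop to 66 this overlap explains was not tested.

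The lists that passed in camera numbered 7 in the knockout, 7 with Setdb1 and 5 in the control, and 3, 1 and 3 with an estimated correlation. Without each library in turn, 7 lists passed in the knockout and 7 with Setdb1, and 5 to 6 in the control. The fall of Ythdf2 in the knockout lay between -0.386 and -0.565 under the alternatives run, leaving out the pseudocount of 5, which compresses changes at low values. Of 344 named values, 307 passed the threshold. A minimum log2 fold change of 1 ended the call for 264, and removal of the libraries with blood transcripts did so for 48 of 215. Adjustment over all protein-coding genes did so for 35, the blood term for 19 and each library left out for 1 to 17.

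Direction reversed for 6 named values. With the overexpression control in place of the knockout, the change against wild type was -0.136 for Egr1 and -0.017 for Psmc5. With the unmodified knockout as comparator, the change with Setdb1 was -0.122 for Btg2, -0.022 for Ccn1 and 0.02 for Ncam1. These follow the difference between the control and the unmodified knockout in those genes. With quantile normalization mt-Nd6 stood at -0.056 with Setdb1, and the cause was not tested.

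The replicate numbers did not pair the libraries. Deviations from the group means correlated at -0.70 to 0.41 between same-numbered libraries, and at -0.06 to 0.21 without the blood markers. Wild-type library 1 correlated best with knockout library 3 (0.77), which also lacked most blood transcripts, and this correlation was -0.02 without the blood markers. With the replicate number as a block, 1586 genes changed in the knockout, 1389 with Setdb1 and 126 in the control, and 9 of 344 named values lost the call. Depth is unknown, so counting error cannot be separated from other spread at low values. Pseudocounts of 0.1 and 5 gave 1593 and 1592 changed genes in the knockout, and the genes with a mean of at least 5 FPKM gave 1202.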

Other observations

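Chosen only after the result was seen were the tests on the origin of the blood transcripts, the test of the knockout lists within the libraries with blood transcripts, the tests of a raised level in the overexpression control, both tests of reversal by Setdb1 and the removal of GC content and length from the motif relation. The 9 lists with fewer than 5 tested members also held large changes in the knockout. The testis somatic genes Sox9 and Clu, markers of Sertoli cells, went from 1.91 ± 0.176 to 0.607 ± 0.0813 FPKM and from 145 ± 1.03 to 70.6 ± 9.16 FPKM and fell, while Inhbb and Gata4 rose (1.44 and 0.29). With Setdb1, Inhbb rose further (0.21) and Gata4 fell (-0.16), a call lost without control library 2 or 3 or Setdb1 library 1 or 2. Of the germline list, Prdm9, the methyltransferase of meiotic recombination sites, fell (-0.53) from 2.95 ± 0.149 FPKM and Cpeb1 rose (0.51), and both changed little with Setdb1 (0.08 and -0.09, adjusted p = 0.251 and 0.254). The endothelial receptor gene Tek rose in the knockout (1.06) and with Setdb1 (0.49), and the macrophage gene Cd68 rose and then fell (0.23 and -0.24).

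Among metalloproteinases and their inhibitors, Adam15 and Timp2 rose in the knockout (0.39 and 0.28) and Timp1 fell (-0.30). With Setdb1 the gelatinase gene Mmp2 rose (0.50) from 41.1 ± 2.53 to 58.6 ± 3.03 FPKM and Timp2 fell (-0.27). The imprinted gene Impact rose in the knockout (0.56) and fell with Setdb1 (-0.37), and the histone gene Hist3h2a did the same (0.56 and -0.85), while the linker histone gene Hist1h1c fell with Setdb1 (-0.42). The immunoproteasome gene Psmb8 fell in the knockout (-0.87) and rose with Setdb1 (0.25). Psmc5, also of the proteasome, rose by 0.07 (adjusted p = 0.0364) and by 0.28, and its first call was lost without wild-type library 2 or 3 or any 1 knockout library. The protocadherin gene Pcdhgc3 did not pass (0.24 and -0.25, adjusted p = 0.193 and 0.196), nor did any of the 4 haemoglobin genes. In the overexpression control Mmp2 rose (0.23, adjusted p = 0.0235), a call lost without control library 1 or 2 or any 1 knockout library, and Hist1h1c fell.

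Of the submitters' 25 terms, which were chosen with these libraries and are not independent evidence, 3 passed in camera in the knockout. Of 291 genes of the cell cycle 160 fell and 71 rose, and of 196 of cell division 115 fell and 47 rose (each adjusted p = 0.00733, and 0.00505 and 0.00546 with an estimated correlation). Of 81 autophagy genes 46 rose and 19 fell (adjusted p = 0.00938, and 0.0207 with an estimated correlation). DNA repair, with 43 of 145 higher and 67 lower, did not pass (adjusted p = 0.654), nor did it with Setdb1, with 51 higher and 47 lower (adjusted p = 0.976). With Setdb1, RNA splicing (59 of 103 higher and 16 lower), mRNA processing (67 of 128 and 23) and focal adhesion (48 of 80 and 15) passed, each at adjusted p = 0.0131 and 0.0167 with an estimated correlation. The transcription factor term passed downward (54 of 224 higher and 92 lower, adjusted p = 0.0234, and 0.0167 with an estimated correlation). With Setdb1 the cell cycle (136 higher and 78 lower) and cell division (97 and 44) did not pass (adjusted p = 0.188 and 0.111), and passed upward with an estimated correlation (adjusted p = 0.0359 and 0.0256). In the overexpression control 0 terms passed in camera, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0662. The target term for the apoptotic process carried the same 257 genes as that for transcription factor activity. The annotation in the same table gave apoptotic process to 2 of these 257 genes and transcription factor activity to 161, so the apoptotic term was not interpreted.

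The 6 libraries of a comparison allow 10 splits, too few for a share under 0.05, and in each of the 3 comparisons 1 split, the real one, gave a result as large. For changed genes the real values were 1594 in the knockout, 1400 with Setdb1 and 179 in the control, and the highest of the other splits were 1, 0 and 2. For lists they were 7, 7 and 5, against 6, 5 and 4. Every other split put libraries of both real groups on each side. The real difference therefore widened the spread within its groups, which leaves few genes to call, and in part stayed between them. These splits are no measure of chance for the genes or the lists. For the 507 genes changed in opposite directions, 1 of 100 splits of both sets of libraries, the real one, gave as many, and the highest other was 0. The calls of the other splits allowed an overlap of at most 1, so their outcome was fixed and says nothing of the overlap. The real count was below the 541.6 genes of independent changes. Independence is not a strict baseline among genes preselected as significant, so the count was not read as above or below chance.

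Blood transcripts in wild-type libraries 2 and 3 and knockout libraries 1 and 2 were recognised from markers of which 5 of 12 red cell, 5 of 14 neutrophil, 4 of 10 platelet and 1 of 9 leukocyte genes were in the table. The 4 haemoglobin genes also form a list of their own, and Itga2b stood at 1.28 FPKM or more in all 12 libraries. Genotype as the cause was argued against by Hbb-bs, which differed 119-fold among the wild-type libraries. A single source for all 4 was argued against by the ratio of Hbb-bs to S100a9, which was 9.48 and 10.7 in wild-type library 2 and knockout library 1 and 2.79 and 2.6 in wild-type library 3 and knockout library 2, a 4.09-fold range. Blood RNA from 2 sources, each shared by a wild-type and a knockout library with like ratios, stays open, since over the 5 platelet and leukocyte markers, which did not set these pairs, the largest distance within them was 1.59 times the smallest between them, and these markers were low (0.13 to 6.18 FPKM).

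The lower mitosis and replication lists and the higher interferon list of the knockout were weighed against a batch marked by blood transcripts and against a bias with GC content or length. In a fit of the 4 libraries with blood transcripts alone, 2 of each group, the largest adjusted p of the 3 lists was 0.00113, and after removal of the trend with GC content and length it was 0.000338. Blood transcripts marked 2 of 3 libraries in both wild type and knockout, so such a batch was balanced between these groups and the first value adds little. The second value argues against GC content or length as the whole cause. A response to loss of the reader may underlie the lists and remains a hypothesis. A difference between the wild-type and knockout lines unrelated to Ythdf2 was not tested, since the other knockout groups carry the same knockout.

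The hypoxia and stress response genes that were lower with Setdb1 were weighed against a raised level in the overexpression control. The median of the 13 stress response genes was -0.753 against the unmodified knockout and -0.746 against the control, which argues against it, while that of the 11 hypoxia genes was -0.20 (median SE 0.03) beside -0.37, which argues against it only as the whole cause, since their median in the control lay 0.17 above the unmodified knockout. Against the unmodified knockout both lists passed in camera (adjusted p = 0.00215 for hypoxia and 0.0147 for the stress response) and missed the threshold with an estimated correlation (adjusted p = 0.0503 and 0.0827), as the stress response list did against the control (adjusted p = 0.0663). After removal of the trend with GC content and length the larger adjusted p of both lists was 0.0188, which argues against that bias as the whole cause. A response to Setdb1 may underlie the change and remains a hypothesis, beside the state of the cultures (density, medium), which the labels do not record and which was not tested.

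A further hypothesis was that Setdb1 acts on the genes that the knockout had lowered. Of 29 mitosis genes lower in the knockout 21 rose with Setdb1, but the list was chosen because it moved both ways, and its counts (29 lower, then 23 higher, of 31) allow no fewer than 21. The one-sided Fisher's exact p of 1.7e-05 against the other lowered genes was therefore fixed in advance and is no evidence of a return. The rise of the list with Setdb1 was itself lost with an estimated correlation (adjusted p = 0.0638). Its median against wild type was -0.37 in the knockout, -0.41 in the control and -0.23 with Setdb1. Of 15 genes of homologous recombination lower in the knockout 4 rose (26.7%), against 271 of 800 others (33.9%, one-sided Fisher's exact p = 0.803). Only 6 of the 21 list members rose with Setdb1, so no more than 6 of these 15 could have risen. The list's own counts thus left the test little room to pass, and no conclusion is drawn from it. The list's median against wild type was -0.32 in the knockout, -0.30 in the control and -0.35 with Setdb1, which argues against a return of the list as a whole.

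If the knockout raised transcripts that carry m6A, its changes might follow the density of the GGACH motif, a sequence at which m6A is found, in the 3′ UTR. Across 1892 of the 2063 genes, which are not independent replicates, the Spearman rho was 0.131 and the Pearson r 0.09 (permutation p = 1e-05, the smallest possible, adjusted p = 3e-05 over 3 comparisons). After removal of GC content and length the rho was 0.06 (permutation p = 0.00895). The density of this motif can itself follow GC content, so the drop does not tell a bias from a relation with the motif. Other properties of the transcripts might share the relation that remained, and m6A itself was not measured here. The rho was -0.06 with Setdb1 (adjusted p = 0.0213), where it missed the threshold after removal of GC content and length (-0.04, permutation p = 0.0508), and -0.04 in the overexpression control (adjusted p = 0.0891).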
